A study of Mus musculus with 2 samples.

How the data were processed

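Trimethylation of lysine 4 of histone H3 (H3K4me3), a mark found at active and poised promoters, was measured by chromatin immunoprecipitation and sequencing in the hindbrain of mouse embryos at embryonic day 14.5. There were 2 biological replicates, each a pool of tissue from embryos of mixed sex, 24 embryos in replicate 1 and 34 in replicate 2, per the labels. Both belonged to a single group, so the comparisons were between the replicates and between classes of genes within the tissue. Groups and replicate numbers were taken from the labels.

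The deposited values were 4 lists of peaks on the mouse build mm10, per the labels. One list was called on each replicate alone against its control, a pooled list on both replicates together, and a replicated list was derived by the authors from these 3, per the deposited file records. Each peak carried a fold enrichment over control, a linear ratio computed by the authors. Each peak also carried its p-value and q-value, which the authors deposited as −log10 values. These values belong to the peak and to its list, and were used here to describe, rank or filter peaks within a list, in the 2 correlations of fold between the replicates, and in percentiles of the change in fold between them. The aligner, the peak caller, their versions and the thresholds used are not given in the sources used here. In the deposited lists the lowest −log10 p was 2.01 in replicate 1 and 2.05 in replicate 2, and the lowest −log10 q was 0.168 and 0.209, so that weak peaks were included. The rule behind the replicated list is not given either. Of the 27354 pooled peaks, 20646 overlapped a peak of each replicate by at least 0.5 of the length of either peak. All 20646 were in the replicated list, and 1171 replicated peaks did not meet that rule. Read depth cannot be told from peak lists and was not known here, so that a weaker replicate could lose peaks or have narrower ones for that reason alone. Signal tracks and alignments were not analysed here.

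Positions were set against the genome GRCm38.p6, which is the same build as mm10, and the GENCODE M21 gene annotation. The end of every peak on chromosomes 1 to 19, X and Y lay within the reference length. Peaks on unplaced scaffolds were kept in overlaps between lists and left out of everything that used genes. The genes were the 21851 protein-coding genes with at least 1 protein-coding transcript in the basic annotation. Genes sharing a symbol were kept apart by gene ID. A gene was called marked when a peak overlapped the window of 1 kb on each side of any of its transcription start sites (TSSs). Peaks separated by gaps of at most 1 kb were merged into domains, and a gene took the width of its widest domain. Broad domains were the widest 5% over marked genes. A peak was distal when it lay more than 5 kb from the TSS of any annotated gene. The ratio of observed to expected CpG was computed from the sequence of the 1 kb windows. A gene took its highest ratio over TSSs, and the classes were high (at least 0.6), intermediate and low (under 0.3).

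A peak of one replicate counted as found in the other when at least 0.5 of its own length was covered by a single peak there. Chance overlap was estimated from 100 seeded placements of the peaks at random on their own chromosomes. Shares carry exact 95% binomial (Clopper-Pearson) intervals, which cover counting error over peaks or genes only. There were 24 gene lists fixed before the data were examined, 22 written gene by gene and 2 defined by symbol patterns. The shares of marked genes and of broad domains in each list were set against all other genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. The median width of each list with at least 3 marked members was placed among 10000 random lists of marked genes with the same CpG classes. A percentile above 97.5 or below 2.5 was counted as outside the random lists. Genes are not replicates, genes that share a domain are not independent, and some genes belong to more than 1 list. The list tests and percentiles therefore describe these libraries, and calls for overlapping lists are not independent of each other. The pattern for transcription factor families also took in a few unrelated symbols, such as Enam and Tbxas1. Of 16 erythroid and blood genes, 15 matched the annotation.

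Genes to be named were set by a rule before the data were examined. It took the 12 genes with the broadest replicated domains (1 per domain, that with the TSS nearest its middle), 2 marked members of each written list with the broadest domains and its first 2 unmarked members in alphabetical order. It added the genes at the 5 replicated peaks of highest fold, the 3 genes per replicate with the broadest domains among those marked in that replicate alone, and the 3 broadest members of each pattern list. Other genes are named where a count is small, at the strongest distal peak or in the closing section, and were chosen after their values were seen.

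The alternatives set in advance were a −log10 q of at least 5, lists of equal length, other overlap rules, TSS windows of 500 bases and 2.5 kb, no merging of peaks and merging over 3 kb, the widest 10% as broad, the pooled list, each replicate alone, and random lists matched on CpG class for the marked shares. Those added after the data were seen were TSSs of all transcripts, each domain counted once, and random lists matched on narrower classes of the CpG ratio. The direct comparisons between Hox groups and between hindbrain and forebrain lists were also added after the data were seen.

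The overlap, list test and width steps were tested on simulated data before use. The overlap step classified 99.9% of simulated peaks rightly and differed from bedtools by 0 peaks. With lists of 20 genes drawn from the 21851 genes, the Fisher test called 67% of lists whose marked share was raised, 90% of those where it was lowered, and 0.222% of unchanged lists. With the 14142 marked genes, doubled widths placed 100% of lists above percentile 97.5, and 6.5% of unchanged lists fell outside the middle 95%. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9.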

Results

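H3K4me3 was profiled in hindbrain from mouse embryos at embryonic day 14.5, in 2 biological replicates pooled from 24 and 34 embryos. The hindbrain at this stage holds dividing progenitors, newborn neurons of the cerebellum, pons and medulla, and non-neural cells of vessels, meninges and choroid plexus. The lists held 27168 peaks in replicate 1, 26150 in replicate 2, 27354 in the pooled data and 21817 called replicated by the authors. They covered 36.5, 37.9, 41.4 and 39.8 Mb of the genome. The median peak was 1050 bases wide in replicate 1, 1181 in replicate 2 and 1604 in the replicated list. The number of reads behind these lists is unknown.

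The first comparison asked how far the replicates located the mark at the same places. The replicates marked nearly the same genes: 14162 protein-coding genes in replicate 1 and 14195 in replicate 2, of which 14063 were marked in both. Only 231 of 21851 genes (1.06%) were marked in one replicate alone, and 42 of these had a peak within 2.5 kb of a TSS in both. Of the genes marked at a TSS in replicate 1 alone, Tchh, Pdia2 and Klhl35 had the broadest domains there (4.98, 3.90 and 3.79 kb). Of those marked in replicate 2 alone they were Gpsm3, Igflr1 and Cldnd2 (4.54, 2.72 and 2.38 kb). Tchh, Klhl35, Igflr1 and Cldnd2 were also marked in the replicated list. In the replicate that marked them, Tchh, Pdia2 and Cldnd2 had folds of 27.1, 34.8 and 33.0, and Klhl35, Gpsm3 and Igflr1 had 3.53, 3.35 and 2.86. In the replicated list the Tchh domain began inside the gene, at 93443180, and the Igflr1 domain ended before its gene start, at 30564543. A small shift of such an edge moves a gene into or out of the 1 kb window. Tchh and Igflr1 therefore need not lack a nearby peak in the other replicate. The Klhl35 domain of the replicated list, from 99465799 to 99469457, covered its gene start at 99466004, so an edge does not account for that gene. All 6 genes had CpG-poor promoters.

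Peaks were found again in the other replicate in most cases. Of the replicate 1 peaks, 22366 (82.3%, 95% interval 81.9 to 82.8) were found in replicate 2, and of the replicate 2 peaks 20881 (79.9%, 79.4 to 80.3) were found in replicate 1. Peaks placed at random gave 1.39% and 1.31%, and at most 1.61% and 1.47% over 100 placements. The 4802 replicate 1 peaks missing from replicate 2 had a median width of 245 bases and a median fold of 3.23, against 1375 bases and 23.5 for those found. Of the missing peaks of replicates 1 and 2, 14.2% and 16.5% lay at a protein-coding TSS, against 64.5% and 67.2% of those found. Over 22366 pairs of peaks, the authors' fold had a rank correlation of 0.80 between replicates (Pearson's r of log2 fold 0.82), a value across peaks, which are not independent replicates. The rank correlation rose to 0.91 among pairs covering at least 0.5 of both peaks. Domain widths over the 14063 genes marked in both replicates had a rank correlation of 0.93.

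The second comparison asked where in the genome the mark lay. Protein-coding promoters held 14034 of the 21817 replicated peaks (64.3%, 63.7 to 65.0). Promoters of long noncoding RNAs held 863, or 3.96% of the 21797 peaks on chromosomes, and those of other gene types 1.89%. The rest had summits in exons (806 peaks), introns (2625) and intergenic sequence (3058). Peaks at protein-coding TSSs had a median fold of 45.6 and a median width of 2088 bases, against 11.5 and 1087 bases at noncoding TSSs and 4.50 and 618 bases in introns. Their summits lay a median of 200 bases downstream of the nearest TSS (quartiles 108 and 313), and 86.5% lay downstream. The share of peaks at a protein-coding TSS was 56.3% ± 0.994 (SD, n = 2) in the single-replicate lists and 53.8% in the pooled list.

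The 5 replicated peaks of highest fold lay at promoters of widely expressed genes. That at Actb, cytoplasmic beta-actin, on chromosome 5 from 142903821 to 142908151, had a fold of 94.8. Peaks shared by Rsf1 and Aamdc (93.1) and by Nudcd3 and A730071L15Rik (92.7), and those at the genes of the RNA-binding proteins Hnrnpr (92.7) and Sfpq (91.3), followed. Distal peaks, more than 5 kb from any annotated TSS, numbered 3199 (14.7%) with a median fold of 5.79. The strongest of them, 12138 bases wide with a fold of 65.3, lay on chromosome 15 from 85669630 to 85681767, 16 kb from a TSS of the noncoding RNA Lncppara, a gene named after its values were seen.

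The third comparison asked which promoters carried the mark. Of 21851 protein-coding genes, 14142 (64.7%, 64.1 to 65.4) had a replicated peak at a TSS, and the share in the single replicates was 64.9% ± 0.107 (SD, n = 2). CpG-rich promoters were marked almost without exception, 8014 of 8080 (99.2%, 99.0 to 99.4). Promoters of intermediate CpG content were marked in 5659 of 6778 genes (83.5%, 82.6 to 84.4) and CpG-poor ones in 469 of 6993 (6.71%, 6.13 to 7.32). Replicates 1 and 2 gave 99.2% and 99.2%, 83.7% and 83.9%, and 6.71% and 7.05%, so that the classes differed by far more than the replicates.

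Among the 24 gene lists, 17 differed from other genes in their marked share by Fisher's exact test at an adjusted exact p under 0.05, with 11 above and 6 below. All 23 pan-neuronal genes were marked (adjusted exact p = 3.66e-04), led by Myt1l, a neuronal transcription factor, and Elavl4, a neuronal RNA-binding protein. All 20 neural progenitor genes were marked (6.63e-04), led by Sox2, which maintains the progenitor state, and Msi1. Of 18 genes of neurotransmitter identity 17 were marked (0.010), the vesicular glutamate transporter Slc17a6 and the vesicular GABA transporter Slc32a1 with the broadest domains, and only Slc17a8 was unmarked. These 3 lists also lay above random lists with the same CpG classes (percentiles 99.4, 98.3 and 98.9).

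Most regional regulators were marked, for the hindbrain and for other brain regions. Marks were present at 22 of 23 genes of the isthmus and hindbrain patterning (adjusted exact p = 1.89e-03), with Pax5 the exception, and at 19 of 20 genes of the cerebellar and rhombic lip lineage (7.25e-03), with the Purkinje cell gene Pcp2 the exception. Of 30 forebrain and midbrain regulators 28 were marked (1.13e-03), Six6 and Tbr1 being the exceptions, and of the marked genes Lhx8, Dlx1 and Fezf2 lacked a TSS peak in replicate 1. None of these 3 lists lay outside the random lists of the same CpG classes (percentiles 79.5, 82.5 and 60.1). Serotonergic genes were marked in 9 of 11 cases (adjusted exact p = 0.380), without Ddc and Tph2, which encode enzymes of serotonin synthesis. Noradrenergic and visceral motor genes were marked in 13 of 15 cases (0.138), without Dbh and Th, which encode enzymes of noradrenaline synthesis. Of these unmarked genes Pax5, Six6, Tbr1 and Tph2 were marked in the pooled list, and Six6 and Tbr1 had peaks of 200 and 457 bases in replicates 1 and 2.

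**Figure D1:**
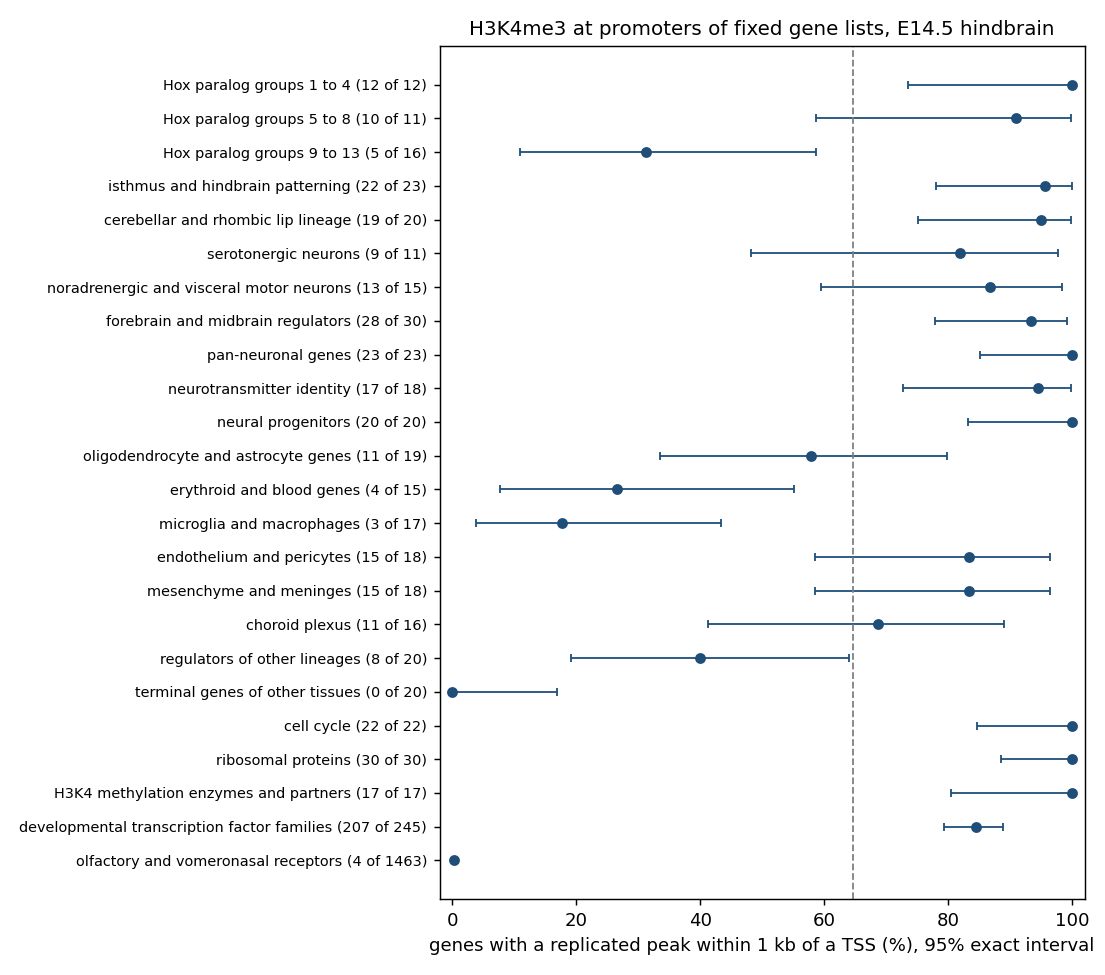
Percent of genes in each of the 24 lists with a replicated H3K4me3 peak within 1 kb of a TSS (x axis, points), with exact 95% intervals as bars and the number marked of those measured beside each name and the 64.7% over all protein-coding genes as a dashed line. Pan-neuronal, progenitor, cell cycle and ribosomal protein genes lie at 100%, and terminal genes of other tissues at 0%.

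Housekeeping lists were marked in full: all 22 cell cycle genes (adjusted exact p = 4.79e-04), all 30 ribosomal protein genes (1.68e-05) and all 17 genes of H3K4 methylation enzymes and partners (2.73e-03). Random lists of the same CpG classes were marked almost as often, and none of the 3 lay outside them (percentiles 87.5, 67.1 and 69.1). Developmental transcription factor families were marked in 207 of 245 genes (84.5%), above other genes (64.5%, adjusted exact p = 6.25e-11). Against random lists of the same CpG classes, with a median of 88.2%, they lay at percentile 0.710, on the other side.

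Genes of other cell types in the dissected tissue varied. Endothelial and pericyte genes were marked in 15 of 18 cases (adjusted exact p = 0.157), including Foxf2 and Kdr, a receptor for vascular endothelial growth factor, and without Emcn and Rgs5. Pecam1, among those marked, lacked a TSS peak in replicate 1. The endothelial and pericyte list lay at percentile 97.9 of the CpG-matched lists, and all 18 genes were marked in the pooled list (adjusted exact p = 1.55e-03). Mesenchyme and meninges genes were marked in 15 of 18 cases (0.157), led by Foxc1 and Pdgfra and without Dcn and Lum, and in the pooled list, where Dcn was marked, they passed the threshold at 94.4% (0.0158). Choroid plexus genes were marked in 11 of 16 cases (adjusted exact p = 1.00), Otx2 and Lmx1a with the broadest domains, and without Aqp1 and Cldn2. Among the marked genes, Ttr (292 bases) lacked a TSS peak in replicate 1 and Slc4a5 (332 bases) in replicate 2. Otx2, Lmx1a and Msx1, the widest of this list, were also members of the forebrain, cerebellar and mesenchyme lists, so their marks are not particular to choroid plexus. Oligodendrocyte and astrocyte genes were marked in 11 of 19 cases (0.659), with Pdgfra and Olig2 the broadest and without Aqp4 and Ermn. The myelin genes differed: Mbp and Cnp, of intermediate CpG content, were marked (fold 44.7 and 23.0), while Plp1, Mog, Mag and Mobp were not. A peak at any annotated TSS counted, and which TSS of Mbp or Cnp carried it was not examined. Every unmarked member had a CpG-poor promoter. With CpG classes matched this list stood above random lists (percentile 99.4), 11 of its 19 genes having CpG-poor promoters.

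Genes of blood cells and microglia, and those listed for other lineages and tissues, were mostly unmarked. Erythroid and blood genes were marked in 4 of 15 cases (26.7%, adjusted exact p = 8.30e-03), namely Tal1, Epor, Klf1 and Gypa, and Alas2 and Epb42 were unmarked. Microglia and macrophage genes were marked in 3 of 17 cases (17.6%, 3.79e-04), namely Sall1, Hexb and Tmem119, of which Tmem119 lacked a peak in at least 1 replicate, with Aif1 and C1qa unmarked. Sall1 and Hexb are also used outside microglia. With CpG classes matched, neither list stood apart (percentiles 43.0 and 11.2). Regulators of other lineages were marked in 8 of 20 cases (0.0455), led by Gata6 and Foxa2, with Hnf1a unmarked and Gata4 marked only in replicate 1 and the pooled list. The list is not foreign to the tissue throughout, since Sox17, which was marked, was also in the endothelial list. Wt1 lacked a TSS peak in replicate 1 and Hnf1b in replicate 2. The call for this list ended with the pooled list (adjusted exact p = 0.184) and with windows of 2.5 kb (0.0851), while the CpG-matched percentile was 0. Terminal genes of other tissues, such as Acta1 and Actc1 of muscle, were marked in 0 of 20 cases (upper limit 16.8%, adjusted exact p = 7.03e-09), although Actc1 had a peak of 207 bases in replicate 2. Of 1463 olfactory and vomeronasal receptor genes 4 were marked (0.273%), against 69.3% of other genes, with a p too small for the software to store. Much of that gap went with promoter class, since 1424 of the receptor genes had CpG-poor promoters. Random lists of the same CpG classes had a median of 8.75% marked (percentile 0). The broadest of the 4 marked receptor genes were Vmn1r4, Olfr94 and Olfr658, with widths of 2.59 ± 0.218, 1.25 ± 0.0156 and 0.379 ± 0.0820 kb (SD, n = 2). Their replicated folds were 45.7, 38.1 and 8.44. The Vmn1r4 domain began at 56922195, before the gene start at 56924015, and 3.03% of it was intergenic, so it also covered another annotated gene. Whether these peaks belong to the receptor genes was not tested.

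The Hox genes, which set position along the body axis from hindbrain to tail, were marked according to their paralog group. All 12 genes of groups 1 to 4, which pattern the hindbrain, were marked (adjusted exact p = 0.0170), and 10 of 11 in groups 5 to 8 (0.140), where Hoxc8 was the exception and all 11 were marked in the pooled list (0.0275). Of 16 genes in groups 9 to 13, 5 were marked (31.3%, adjusted exact p = 0.0121): Hoxb9, Hoxd9, Hoxa13, Hoxd13 and Hoxc10. Against random lists of the same CpG classes the call for groups 1 to 4 ended (percentile 88.5), groups 5 to 8 lay at percentile 34.5, and groups 9 to 13 stayed below all random lists (percentile 0). Hoxa10 and Hoxa11 were unmarked in both replicates. Groups 1 to 8 and 9 to 13 differed, with 22 of 23 against 5 of 16 marked (exact p = 2.62e-05 by Fisher's test, added after the data were seen). The pooled list marked 9 of 16 genes in groups 9 to 13, which ended their difference from other genes (adjusted exact p = 0.479), while the difference between the Hox groups kept an exact p of 7.44e-04. In replicate 2 alone, 91.7% of groups 1 to 4 were marked, Hoxb1 lacking a peak, and the adjusted exact p was 0.0904.

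The widest domain of the genome, 63.9 kb on chromosome 11 from 96291625 to 96355513, ran over Hoxb2, Hoxb3, Hoxb4, Hoxb5 and Hoxb6. It was 18.1% exonic, 49.7% intronic and 32.2% intergenic, and the domain at Hoxb3 measured 60.1 ± 7.01 kb (SD, n = 2). A gap set Hoxb2 apart from it in replicate 1, where its own domain was 6.99 kb, against 65.0 kb in replicate 2. On chromosome 6 a domain of 29.6 kb from 52156428 to 52186051 covered Hoxa1 and Hoxa2, and another of 25.9 kb from 52187461 to 52213382 covered Hoxa3, Hoxa4, Hoxa5 and Hoxa6. In replicate 1 a single domain of 53.9 kb covered the TSSs of all of these but Hoxa3, whose domain measured 2.05 kb. On chromosome 2, Hoxd3 and Hoxd4 shared a domain of 18.1 ± 2.25 kb. Median widths were 21.2 ± 6.63 kb for groups 1 to 4 (16.5 kb in replicate 1, 25.9 in replicate 2), 7.48 ± 0.639 kb for groups 5 to 8 (10.7 kb in the replicated list, 7.03 in replicate 2) and 0.735 ± 0.226 kb for groups 9 to 13 (SD, n = 2). Each replicate's median was over the genes marked in that replicate. For groups 9 to 13 these took in Hoxd10 in replicate 1 and Hoxb13 in replicate 2. The medians of groups 1 to 4 and 5 to 8 lay at percentile 100 of the CpG-matched random lists and that of groups 9 to 13 at 0. Hoxb9 and Hoxd9, the widest of groups 9 to 13, measured 2.03 ± 0.111 and 1.31 ± 0.282 kb.

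**Figure D2:**
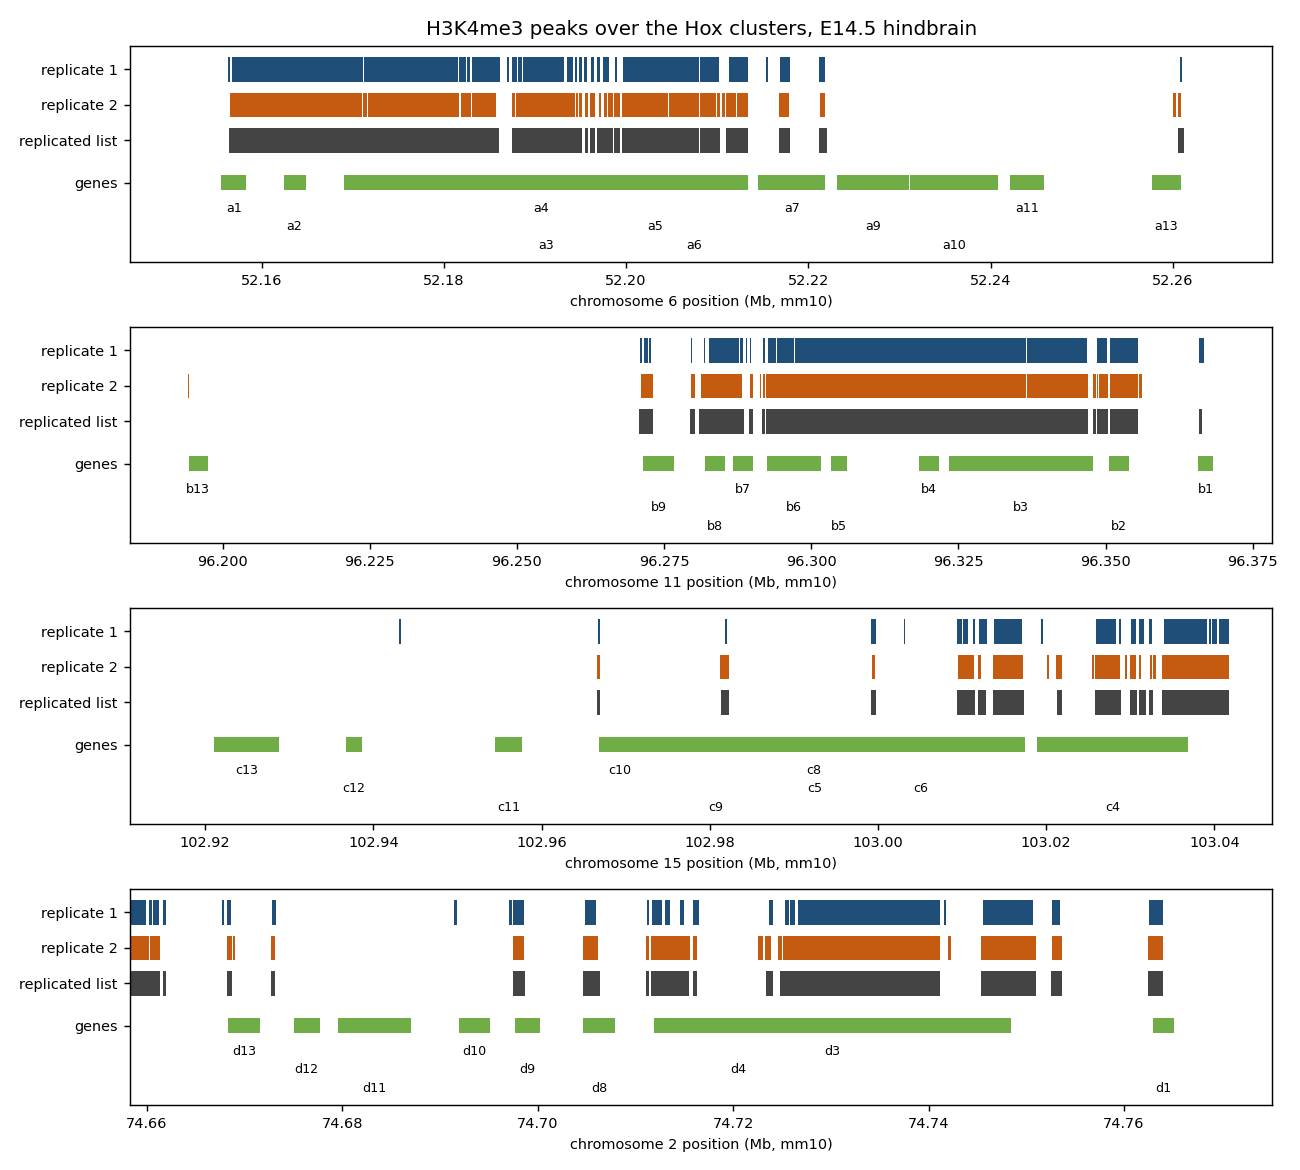
Peaks over the Hoxa, Hoxb, Hoxc and Hoxd clusters in replicate 1, replicate 2 and the replicated list (bars to scale, x axis in Mb of mm10), with the genes in green and named without their prefix. The wide blocks cover paralog groups 1 to 6 of Hoxa and 2 to 6 of Hoxb, and the bars over groups 9 to 13 are few and narrow.

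The fourth comparison asked which genes carried broad domains. The median width over the 14142 marked genes was 2.29 kb, and in the single replicates it was 2.18 ± 0.0290 kb (SD, n = 2). The widest 5% were 708 genes of at least 5.37 kb. Below, medians with an SD are over the single replicates, and percentiles and broad counts are those of the replicated list unless a replicate is named. The median of a single replicate is over the list genes marked in that replicate, which can differ between the replicates. Among protein-coding genes outside the Hox clusters, Meis2, a cofactor of Hox proteins, had the broadest domain, 27.2 ± 0.387 kb on chromosome 2 from 116049570 to 116076539, 51.8% of it intronic. Nr2f2, an orphan nuclear receptor, had 25.2 ± 0.135 kb, and the neuronal transcription factors Ebf3 and Pou3f3 had 23.3 ± 0.0573 and 22.5 ± 1.37 kb. Lhx1 and Lhx5, LIM homeodomain factors of Purkinje cell precursors, had 21.7 ± 0.236 and 17.5 ± 0.0318 kb, and Nfib had 20.4 ± 1.39 kb. Zic1 and Zic4 shared a domain of 26.2 kb in the replicated list and of 15.7 ± 0.566 kb in the single replicates.

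Broad domains were more frequent than among other genes in 10 of the 24 lists. These calls are not separate results, because the lists share members. The transcription factor pattern took in every Hox gene and genes such as Meis2, Lhx1 and Sox2, and Lmx1b was in both the hindbrain patterning and the serotonergic list. Of marked genes of the isthmus and hindbrain patterning, 15 of 22 (68.2%) had broad domains, against 4.91% of other genes (Fisher's exact test, adjusted exact p = 3.97e-14). The median width was 7.86 ± 0.266 kb (SD, n = 2), with Meis2 and Lmx1b (13.3 and 16.8 kb in the replicates) at the top. The cerebellar and rhombic lip lineage had 11 of 19 (57.9%, 1.44e-09) and a median of 6.35 ± 0.113 kb. Hox groups 1 to 4 had 10 of 12 (4.48e-11) and groups 5 to 8 had 8 of 10 (6.25e-09), and with each shared domain counted once 5 of 7 (2.06e-05) and 4 of 6 (2.59e-04), while none of the 5 marked genes of groups 9 to 13 had one (adjusted exact p = 1.00).

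Neural progenitor genes had broad domains in 11 of 20 cases (2.45e-09), with a median of 5.54 ± 0.397 kb. Sox2 measured 16.9 kb in replicate 1 and 11.1 kb in replicate 2, and Msi1 8.98 ± 0.124 kb. Pan-neuronal genes had 10 of 23 (2.01e-07) and a median of 5.07 ± 0.121 kb, with Myt1l at 13.7 ± 0.0262 kb and Elavl4 at 11.9 ± 0.209 kb. Genes of neurotransmitter identity had 8 of 17 (1.85e-06) and a median of 3.92 ± 0.631 kb, with Slc17a6 at 13.5 ± 0.164 kb and Slc32a1 at 11.7 and 12.4 kb in the replicates. Developmental transcription factor families had 80 of 207 (38.6%, against 4.51% of other genes, 4.53e-49) and a median of 3.70 ± 0.410 kb. Each of these 4 lists lay at percentile 100 of the CpG-matched random lists, in the replicated list and in each replicate.

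Serotonergic genes had 3 broad domains among 9 (33.3%, adjusted exact p = 0.0201), with a median of 3.92 ± 0.109 kb (percentile 99.4). These were Lmx1b, Gata2 (8.98 ± 0.310 kb) and Gata3 (8503 bases in replicate 1, 18470 in replicate 2). The call ended without merging of peaks (22.2%, adjusted exact p = 0.156) and with the widest 10% taken as broad (33.3%, 0.103), and the percentile fell to 21.8 without merging and to 43.2 with the stricter q-value. Noradrenergic and visceral motor genes had 3 broad domains among 13 (23.1%, adjusted exact p = 0.0535), including Tbx2 (7.07 ± 0.502 kb, and 13.1 kb in the replicated list) and Tlx3 (10.8 ± 0.363 kb). They passed the threshold in replicate 2 alone (38.5%, adjusted exact p = 7.57e-04), in the pooled list (38.5%, 7.62e-04), with gaps of up to 3 kb merged (30.8%, 7.43e-03) and with each domain counted once (0.0428). Their median width was 2.11 kb in replicate 1, 3.18 kb in replicate 2 and 2.03 kb in the replicated list. The percentile of 14.2 in the replicated list was 98.6 in replicate 2 alone and 99.0 in the pooled list.

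Forebrain and midbrain regulators, nearly all marked, had a low median width, yet broad domains more often than other genes. Their median was 1954 bases in the replicated list, at percentile 0.415 of the CpG-matched random lists, and 1862 and 1502 bases in replicates 1 and 2 (percentiles 1.55 and 0). Broad domains covered 6 of 28 (21.4%), above the 4.97% of other genes (adjusted exact p = 6.01e-03 by Fisher's test). Bcl11b (9.51 ± 0.0983 kb) and Lhx2 (9.38 ± 0.149 kb) were the broadest, and the call ended without merging of peaks (14.3%, 0.121). The share was lower than the 15 of 22 of the hindbrain list (exact p = 1.40e-03 by Fisher's test, added after the data were seen, and 8.25e-03 and 1.30e-03 in the single replicates). The low median did not hold under wider merging: with gaps of up to 3 kb merged the list moved to percentile 98.8, and in the pooled list it lay at 5.05.

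**Figure D3:**
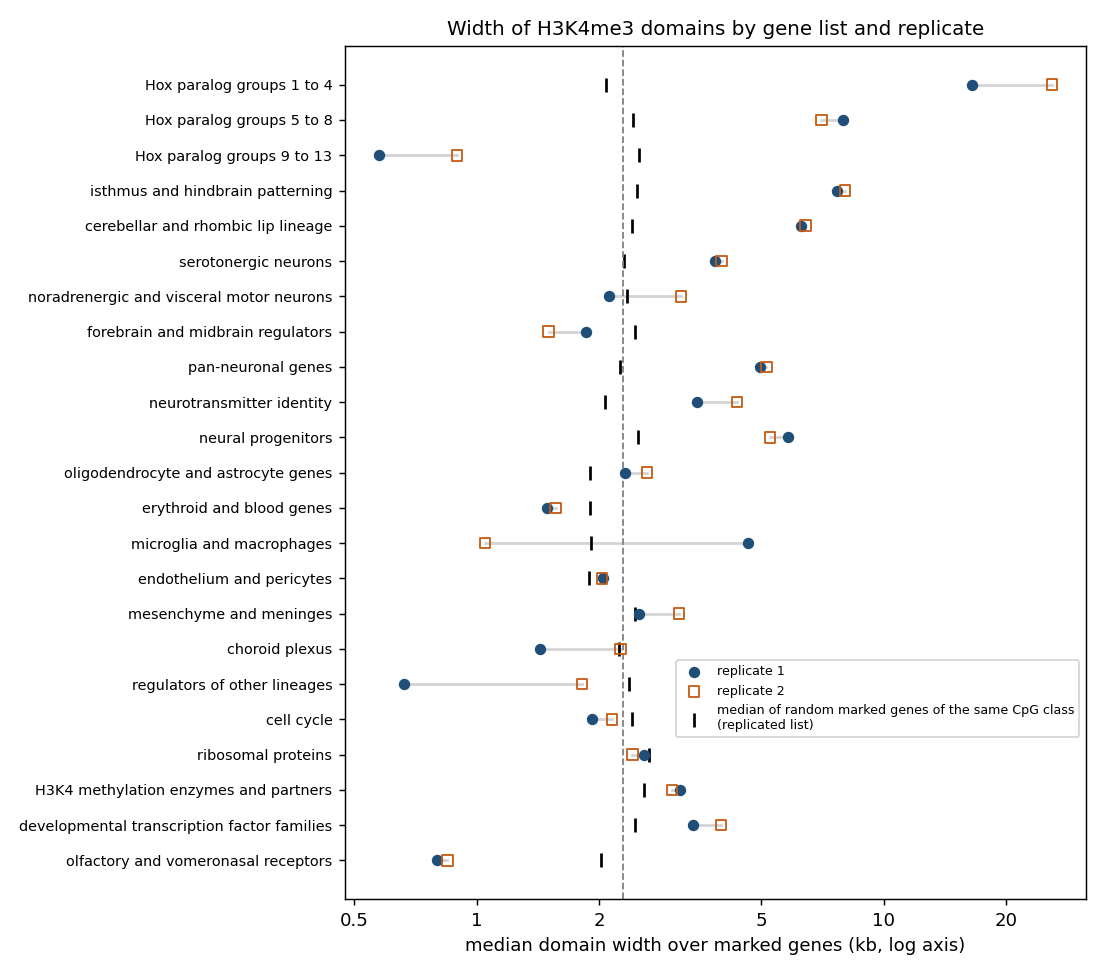
Median domain width over the marked genes of each list in replicate 1 (filled circles) and replicate 2 (open squares), in kb on a log axis, with medians from the replicated list for random marked genes of the same CpG classes (black ticks) and for all marked genes (dashed line, 2.29 kb). Hox groups 1 to 4 lie at 16.5 and 25.9 kb, hindbrain patterning genes at 7.67 and 8.04 kb, and forebrain and midbrain regulators at 1862 and 1502 bases.

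Housekeeping genes had domains of ordinary width. Cell cycle genes had a median of 2.34 kb in the replicated list (percentile 37.0), and of 2.03 ± 0.161 kb in the single replicates (6.00 and 22.6), with Pcna at 3.29 ± 0.0615 kb and Rrm2 at 2.66 ± 0.371 kb. Ribosomal protein genes had 2.62 kb (percentile 44.3) and 2.49 ± 0.113 kb (59.6 and 25.1), with Rpl18 at 5.26 ± 0.0601 kb and Rpl7 at 4.57 ± 0.148 kb. None of the 22 and none of the 30 genes had a broad domain (adjusted exact p = 0.790 and 0.610). Of the H3K4 methylation enzymes and partners 2 of 17 did (0.357), the methyltransferase genes Setd1b (14.4 ± 0.119 kb) and Kmt2d (5.21 ± 0.395 kb). The median of that list was 3.09 ± 0.105 kb (percentile 91.2, and 97.7 in replicate 1 alone).

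Few domains at genes of non-neural and glial cells were broad. Mesenchyme and meninges genes had a median of 2499 bases in replicate 1 and 3141 in replicate 2, with Foxc1 at 6.29 and 7.92 kb, and 2 of 15 were broad (adjusted exact p = 0.316). Their percentile of 97.8 in the replicated list was 71.9 in replicate 1 alone, 86.9 in the pooled list, 45.2 with the stricter q-value and 49.5 without merging. Endothelial and pericyte genes had a median of 2.04 ± 0.00566 kb (percentile 83.1) and 1 broad domain in 15 (0.716), that of Foxf2 (6.13 ± 0.964 kb), while Kdr measured 3.84 ± 0.0552 kb. Oligodendrocyte and astrocyte genes had 2.31 and 2.62 kb in the replicates (percentile 97.0, 91.9 and 97.49 in replicates 1 and 2 alone, and 97.7 to 99.3 under 3 other alternatives) and 1 in 11 (0.610), that of Pdgfra (6.23 ± 0.357 kb), while Olig2 measured 7.13 kb in replicate 1 and 4.77 kb in replicate 2.

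The remaining lists were small. Choroid plexus genes had a median of 1.43 and 2.26 kb in the replicates (1503 bases in the replicated list) and 1 broad domain in 11 (adjusted exact p = 0.610), at Otx2 (10.7 kb in replicate 1, 6.24 kb in replicate 2), with Lmx1a at 5.57 ± 1.37 kb. Their percentile was 0.835, and 54.0 in replicate 2 alone and 3.83 with the stricter q-value. The 4 marked erythroid and blood genes had 1.53 ± 0.0534 kb (percentile 24.6) and no broad domain (1.00), with Tal1 at 8.55 kb in replicate 1 and 4.82 kb in replicate 2, and Epor at 1.66 ± 0.0672 kb. Of 3 marked microglia genes (percentile 9.07, and 1.21 in the pooled list) 1 had a broad domain (0.286), Sall1 with 9.10 ± 1.26 kb, and Hexb measured 1.06 ± 0.0106 kb. The 8 marked regulators of other lineages had a median of 1451.5 bases in the replicated list and no broad domain (1.00). Their percentile was 0.160, and 14.7 in replicate 2 alone and 48.4 with the stricter q-value. The medians of 662 bases in replicate 1 and 1817 in replicate 2 were over different genes. Gata4 and Hnf1b counted only in replicate 1, and Wt1 only in replicate 2. Over the 6 genes with a domain in both, the median log2 ratio of width, replicate 2 over 1, was 0.02. Gata6 measured 3.12 ± 0.0198 kb and Foxa2 2.84 ± 0.478 kb. The 4 marked olfactory and vomeronasal receptors had 0.823 ± 0.0339 kb (percentile 0.130) and no broad domain (1.00).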

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

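The count below was looked at because these peaks lie outside the chromosomes used in the comparisons. The replicated list held 20 peaks on 10 unplaced scaffolds. No number was expected for them, so that the count alone shows nothing unusual. They made up 0.0917% of the list, with a median fold of 5.34, a highest fold of 48.0 and a median width of 618.5 bases. Replicate 1 held 40 such peaks, replicate 2 held 35 and the pooled list 48. The scaffold peaks carry no gene results in the comparisons, and no biological explanation for them was tested.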

How the results depend on the processing

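The alternatives chosen only after the data were seen were TSSs of all transcripts, each domain counted once and random lists matched on narrower CpG classes. The share of replicate 1 peaks found in replicate 2, the share of replicate 2 peaks found in replicate 1 and the rank correlation of fold were 95.6%, 90.2% and 0.83 with a −log10 q of at least 5. They were 84.4%, 79.3% and 0.80 with lists of equal length, 86.9%, 85.5% and 0.77 with any shared base, and 72.8%, 75.7% and 0.91 with 0.5 of both peaks. The share of genes marked was 64.5% with the stricter q-value, 64.2% and 65.7% with windows of 500 bases and 2.5 kb, 65.5% in the pooled list, 65.7% with TSSs of all transcripts and 64.8% to 65.0% in single replicates. The share of peaks at a protein-coding TSS was 66.8%, 63.1%, 69.3% and 53.8% under the first 4 of these and 55.6% to 57.0% in single replicates. High-CpG promoters were marked in 99.1%, 99.1%, 99.3% and 99.4% (99.2% to 99.2% in single replicates), intermediate ones in 83.1%, 82.9%, 84.1% and 84.8% (83.7% to 83.9%) and low-CpG ones in 6.39%, 5.79%, 9.02% and 7.71% (6.71% to 7.05%).

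Of the 24 lists, 17 were called for marked share. Set against random lists matched on CpG class 10 were, and 8 were called both ways. Against those lists the oligodendrocyte and astrocyte genes lay at percentile 99.4 and the developmental transcription factor families at 0.710, each on the other side from the Fisher test. Width percentiles changed side for the serotonergic list (43.2 with the stricter q-value, 21.8 without merging) and for the mesenchyme and meninges list (45.2 and 49.5). They also did for the noradrenergic and visceral motor list (38.3 and 98.6 in replicates 1 and 2 alone, 99.0 in the pooled list, 100 with gaps of 3 kb merged), for choroid plexus (0.535 and 54.0 in replicates 1 and 2 alone) and for the forebrain and midbrain list (98.8 with gaps of 3 kb merged). The cause was not tested. Of the comparisons by list, 173 of marked share, 223 of broad share and 136 of width percentile kept their direction and side of the threshold. In the same direction, 13, 3 and 10 lost a call and 4, 4 and 5 gained one. A further 2 of marked share and 9 of width percentile changed direction, and calls were lost or gained among these too. Median widths in bases, which carry no call, were counted as moved in 155 comparisons and as the same in 229. No paired analysis was possible because the replicates form a single group. Read depth was unknown, so that its part in the differences between lists could not be measured.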

Other observations

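The genes in this part were chosen after their values were seen. Of 747 domains at a long noncoding RNA TSS without a protein-coding TSS, 31 reached the broad threshold. The broadest, at C130071C03Rik on chromosome 13, measured 29.4 ± 0.0615 kb (SD, n = 2). It was followed by Mir124-2hg, a host of the neuronal microRNA miR-124, with 17.7 ± 0.660 kb, Gm3764 with 15.2 ± 0.409 kb, Mir9-3hg, a host of miR-9, with 13.7 ± 0.869 kb and 3110039I08Rik with 12.4 ± 0.303 kb. Malat1, a widely expressed nuclear noncoding RNA, had 9.74 ± 0.609 kb, and Mir124a-1hg, another host of miR-124, had 9.50 ± 0.149 kb. Whether noncoding RNAs of the nervous system were more frequent among these domains was not tested.

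Of the 469 CpG-poor promoters that carried the mark, the broadest domain was that of Kdm6b, a histone demethylase, with 12.8 ± 0.479 kb (SD, n = 2). Myt1, a neuronal transcription factor, had 7.40 ± 0.0686 kb, Adarb2, a member of the RNA-editing enzyme family, 7.12 ± 0.0396 kb, Dlg4, which encodes the postsynaptic protein PSD-95, 6.81 ± 0.0431 kb, and Prrt1 6.34 ± 0.0184 kb. Of the 66 CpG-rich promoters without a replicated peak, 8 belonged to Hox genes of groups 9 to 13, 8 to histone genes, 3 to the protocadherin alpha cluster and 18 to numbered gene models. The germline genes Ddx4, Sycp1, Mael, Taf7l and Meioc were also among them. The pooled list marked 14 of the 66.

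The tests of weak peaks and of repeat sequence below were chosen only after the result was seen. Peaks of one replicate missing from the other were mainly weak. Some of them shared fewer bases than the rule asked: with any shared base 86.9% and 85.5% of replicate 1 and 2 peaks were found, against 82.3% and 79.9%. Among peaks with a −log10 q of at least 5, 2.37% in replicate 1 and 5.87% in replicate 2 were missing from the full list of the other, against 17.7% and 20.1% of all peaks. Missing peaks already had a median −log10 q of 2.23 and 3.10, against 97.8 and 152 for those found. The filter thus had to lower the missing share, and it describes these peaks without testing a cause. Repeat sequence was more frequent among missing peaks away from protein-coding TSSs than among shared ones, by up to 3.36 times, but at most 4.44% of missing peaks were mostly repeats, which argues against repeats as the main source. Weak peaks near the authors' threshold are a candidate explanation that stays open, as does a smaller part of repeats. The design holds a single group, and no biological explanation was tested.

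The tests with each domain counted once and with narrower CpG classes were chosen only after the data were seen. Developmental transcription factors had broad domains more often than other genes. Without merging of peaks their broad share was still 6.92 times that of other genes (31.9% against 4.61%), and with each domain counted once it was 7.67 times (34.9% against 4.55%). Their median width of 3915 bases lay at percentile 100 of random genes matched on narrower CpG classes, whose median was 2521 bases. These values argue against merging, clusters and CpG content as the whole source, while read depth stayed untested and no biological explanation was tested.

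The tests of a general width difference and of fold, and the second gene list, were chosen only after the result was seen. Mesenchyme and meninges genes, picked from 22 lists for this ratio, had wider domains in replicate 2, with a median log2 ratio of 0.33 over 15 genes against 0.03 over all genes. With gaps of 3 kb merged the median log2 ratio fell to 0.20, and the list lay at percentile 99.9 of random lists matched on width. This argues against domains broken up in replicate 1 as the whole source, while a part of the ratio went with the merging. A second mesenchyme list of 30 genes, written before its own values were seen, lay at percentile 99.7 (log2 ratio 0.19 over 25 genes). This argues against a difference shared alike by all genes of the same width. The random lists were not matched on fold, and some members had very narrow domains in replicate 1, such as Islr (208 bases) and Lamc3 (217). Read depth was unknown, so the test cannot exclude a general difference that acts more on weakly enriched domains. Of the 22 lists, 4 lay outside random lists for width, among them Hox groups 1 to 4 (99.8) and 5 to 8 (0.0600) and ribosomal proteins (0.570), while for fold the mesenchyme lists lay within them (48.1 and 53.2), endothelial and pericyte genes above (99.2) and forebrain and midbrain regulators below (0.630). A larger share of mesenchyme in the replicate 2 pool is 1 candidate explanation, met by the widths and not by the fold, and it stays open.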
